A study of Homo sapiens with 12 samples.

How the data were processed

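Total RNA from human monocyte-derived macrophages, primary cells grown from blood monocytes, was measured on 12 Illumina bead arrays. The samples formed 4 groups of 3 arrays, taken from the sample titles. The groups were vehicle (DMSO, 1%), the compound LA1 at 20 µM, lipopolysaccharide (LPS, a component of the bacterial outer membrane that activates macrophages), and LPS together with LA1. DMSO is given for the vehicle group only, so whether the other groups also held it is unknown. The labels differ on the exposure. The sample labels give LPS at 100 ng/mL for 4 h, while the series' design text gives 50 ng/mL and names both 8 h and 4 h, so the dose and time of LPS stay unsettled. LA1 is known here only by its code name. Per the labels' protocols, the RNA was column-purified after Trizol, treated with DNase, and amplified to biotinylated cRNA.

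The values used were the authors' deposited table of 47229 probes, read as log2 values. On the deposited log2 scale each probe was centred on its own median over the 12 arrays, which was 0 within 0.005 for every probe. The base of the logarithm, the background correction and the normalization between arrays are not given in the sources used here. Every fold change below assumes base 2. Centred values hold differences between arrays and no levels, so no probe could be called present or absent, and how far background compresses the changes of weakly expressed genes is unknown. The median of every array's column was 0. A table of signals before normalization was used for no result here, because the names of its 24 value columns match no sample label. The tests planned before the data were examined assumed those signals, with a background correction, quantile normalization and a filter on detection. The values as deposited replaced them, with no filter on dim probes.

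Probes were named through the platform annotation given with the table, with symbols checked through Entrez identifiers against RefSeq gene names. Of the probes, 30113 had 1 gene symbol, 8 had several and 17108 were not listed there and stay unnamed here. XIST, TSIX and genes of the Y chromosome were left out of every step. This gave 19951 genes, of which 6659 had several probes. The plan had been to take the probe with the highest mean signal for each gene. Centred values have no such mean, so the probe with the largest variance over the 12 arrays was taken, a rule set after the table was seen. This rule favours probes that vary between arrays. Among the 24 genes named for LPS against DMSO, 12 had several probes, and all probes passed in the same direction for 11 of these. For LA1 against DMSO this held for 4 of 5 such genes, for LPS+LA1 against LPS for 3 of 3, for LPS+LA1 against LA1 for 1 of 2 and for the interaction for 2 of 2.

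Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) to all 12 arrays, with 4 group means, 8 residual degrees of freedom and no block. P-values were adjusted with the Benjamini-Hochberg method over the 19951 genes, with a threshold of 0.05. Errors of log2 changes are the moderated SE, with n = 3 arrays per group. The comparisons were LPS against DMSO, LA1 against DMSO, LPS+LA1 against LPS, LPS+LA1 against LA1, and the interaction, which subtracts the LA1 effect without LPS from the LA1 effect with LPS. Gene lists, 42 in number and fixed before the data were examined, were tested with camera (preset correlation 0.01, adjusted over the 42 lists), with an estimated correlation as an alternative. They covered 767 entries, of which 711 were measured. All values below come from 3 arrays per group, whose number limits the precision. The median SD between replicates of a gene was 0.0520, and no array duplicated another. The labels do not say that replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

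The genes named for the 3 main comparisons were the 12 with the largest increases and the 12 with the largest decreases among genes past the threshold whose 2 groups did not overlap. For LPS+LA1 against LA1 and the interaction, 5 each way were named. From each list named, up to 4 members with the smallest p were eligible, and the member with the largest p as a counterexample. Genes without an official symbol were passed over. LPS-induced genes were also measured on arrays that had not been used to choose them, though each gene's probe had been chosen on all 12 arrays. Genes higher by at least 1 on the log2 scale were chosen on the arrays of 2 replicate numbers. Their median change was read from the third. Genes lower by as much were treated alike, a measurement added after the results were seen, as was the count of simulated genes at an unadjusted p. The genes in the plots and the lists averaged per array were picked after their values were seen. Figures were drawn with matplotlib 3.10.9.

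The fit was tested on simulated data made from the residuals of the 12 arrays, with 200 genes changed in the LPS against DMSO comparison of 19951 genes. Of the genes changed by 0.1 on the log2 scale 0% were recovered, of those changed by 0.25 92%, and of those changed by 0.5 or by 1 100%. Of the calls, 2.67% were genes that had not been changed. The residuals of each probe were shuffled over the arrays separately, so these data held no error shared between genes or over a whole array. The rate does not cover such errors. Alternatives covered the choice of probe, a replicate block, the arrays in the fit, the variance model, array weights, a 2-fold limit, leaving out arrays, scaling of the arrays on 11 housekeeping genes, and a filter that kept genes with a range of at least 0.5 over the arrays, the last pair added after the data were seen.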

Results

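The series measured gene expression in human macrophages given LPS in the absence or presence of LA1, with vehicle and LA1 alone as controls. Since DMSO is given for the vehicle group only, a difference in vehicle may enter the comparisons below. It cannot be told apart from the treatments. Each of the 4 groups had 3 arrays, and replicates lay close together: the 95th percentile of the pooled replicate SD of a gene was 0.0818 on the log2 scale. Values are differences on the centred log2 scale with no absolute level, and the number of arrays limits their precision.

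LPS against DMSO gives the response of the macrophages to LPS. CXCL10, a chemokine that draws activated T cells, was 107-fold higher (log2 change 6.74 ± 0.0413, SE, n = 3 per group, adjusted p = 7.77e-38), CCL20 was 60.1-fold higher (5.91), and IDO1, which degrades tryptophan, was 55.8-fold higher (5.80). OASL (5.61), IFIT1 (5.29), IFIT2 (5.19), IFIT3 (4.92) and the exonuclease gene ISG20 (5.28), all interferon-induced antiviral genes, rose with ACOD1 (5.46), which makes itaconate, the chemokines CXCL8 (5.22) and CCL5 (5.22), and TNFAIP6 (4.94). The largest decreases were those of CEBPA, a transcription factor of myeloid cells (−2.71), MERTK, a receptor for the uptake of dying cells (−2.25), and the lipid-droplet coat gene PLIN2 (−2.16). FOS (−2.08), PDK4, an inhibitor of pyruvate dehydrogenase (−1.90), RASL11B (−1.74), SNORA61 (−1.70), DYRK2 (−1.66), CHD9 (−1.65), the metallothionein gene MT1X (−1.62), RGS2 (−1.61) and PRAG1 (−1.55) followed, and 3 of the 4 DYRK2 probes passed. The SE of these 24 changes ran from 0.0380 to 0.0502. The 2 groups did not overlap for 43.3% of all genes, against 10% by chance.

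All 32 measured genes of the type I interferon response list were higher with LPS, with a median log2 change of 2.64 (camera, adjusted p = 1.63e-60), from OASL at 5.61 to IFI6 at 0.85. All 19 genes of the NF-kB feedback and subunits list were higher (median 1.41, adjusted p = 7.88e-30), among them TRAF1 (3.93), NFKBIZ (3.12) and TNIP3 (2.66). Of 19 pro-inflammatory cytokines 16 were higher and 1 lower (adjusted p = 2.59e-20), with IL6 at 4.69, IL1B at 4.61, TNF at 4.59 and IL1A at 3.69, while IL19 had a log2 change of 0.06. Of 24 chemokines 19 were higher and 1 lower (adjusted p = 4.27e-23), CCL8 among them (4.85). Of 20 antigen presentation and costimulation genes 12 were higher and 3 lower (adjusted p = 2.80e-07), led by CD80 (2.88), CD40 (2.41) and CD83 (2.01). Of 22 antimicrobial effectors 9 were higher and 3 lower (adjusted p = 6.56e-05), including complement factor B, CFB (4.09), and the mitochondrial dismutase SOD2 (2.98). The numbers of higher genes adjusted over the list alone were 32 interferon, 19 NF-kB, 17 cytokine, 19 chemokine, 12 antigen presentation and 9 antimicrobial genes. With the arrays scaled on housekeeping genes 32, 19, 18, 22, 17 and 17 were higher in these 6 lists, and 0, 0, 0, 0, 1 and 3 lower.

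Genes of mitochondrial respiration and of the cell cycle were lower with LPS by small amounts. Of 20 oxidative phosphorylation genes 17 were lower and 0 higher (median −0.23, adjusted p = 0.000395), led by NDUFS3 (−0.60), and with housekeeping scaling 8 were lower and 1 higher (median −0.09). Of 22 cell cycle genes 18 were lower and 1 higher (median −0.30, adjusted p = 7.32e-06), with AURKA at −0.99 and CDC20 at −0.78, and with that scaling 13 were lower and 4 higher (median −0.16). In these 2 lists 17 and 18 were lower adjusted over the list alone. Of 18 macrophage and monocyte markers 11 were lower and 4 higher (adjusted p = 0.01001; 12 lower adjusted over the list alone), with CSF1R at −0.70 and CD14 at −0.69, and with that scaling 9 were lower and 5 higher. That list did not pass among genes with a range of at least 0.5 over the arrays (adjusted p = 0.202, 0.000763 to 0.202 over its 7 camera alternatives). Markers of other cell types moved with the same arrays. Of 15 T cell markers 6 were higher and 0 lower (adjusted p = 0.000759), with the interleukin receptor gene IL7R at 2.35 and CD8A at 0.63. Of 13 NK cell markers 6 were higher and 0 lower (adjusted p = 0.00251), with GZMB at 0.80. Of 14 dendritic cell markers 3 were higher, LAMP3 (3.60), CCR7 (2.53) and BATF3 (1.45), and 11 did not pass (adjusted p = 0.00808). These 3 counts were 6, 6 and 3 adjusted over the list alone. Markers of B cells (adjusted p = 0.329), neutrophils (0.650) and platelets or erythroid cells (0.512, with a negative median and a positive mean and test) did not pass as lists. With housekeeping scaling 13 T cell, 10 NK cell, 11 dendritic cell, 10 B cell and 11 neutrophil markers were higher and 0 lower, and platelet and erythroid markers turned from 1 higher and 2 lower to 12 higher and 1 lower.

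At least 2-fold changes were seen for 478 genes, 393 higher and 85 lower. Without that limit 7607 genes passed, 2607 higher and 5000 lower (65.7% lower), and with the arrays scaled on housekeeping genes 14188 passed, 11357 higher and 2831 lower (20.0% lower). That scaling moved the median change of all genes to 0.12 and left 457 genes at least 2-fold higher and 47 lower, so the balance of small changes depends on the scaling.

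**Figure D1:**
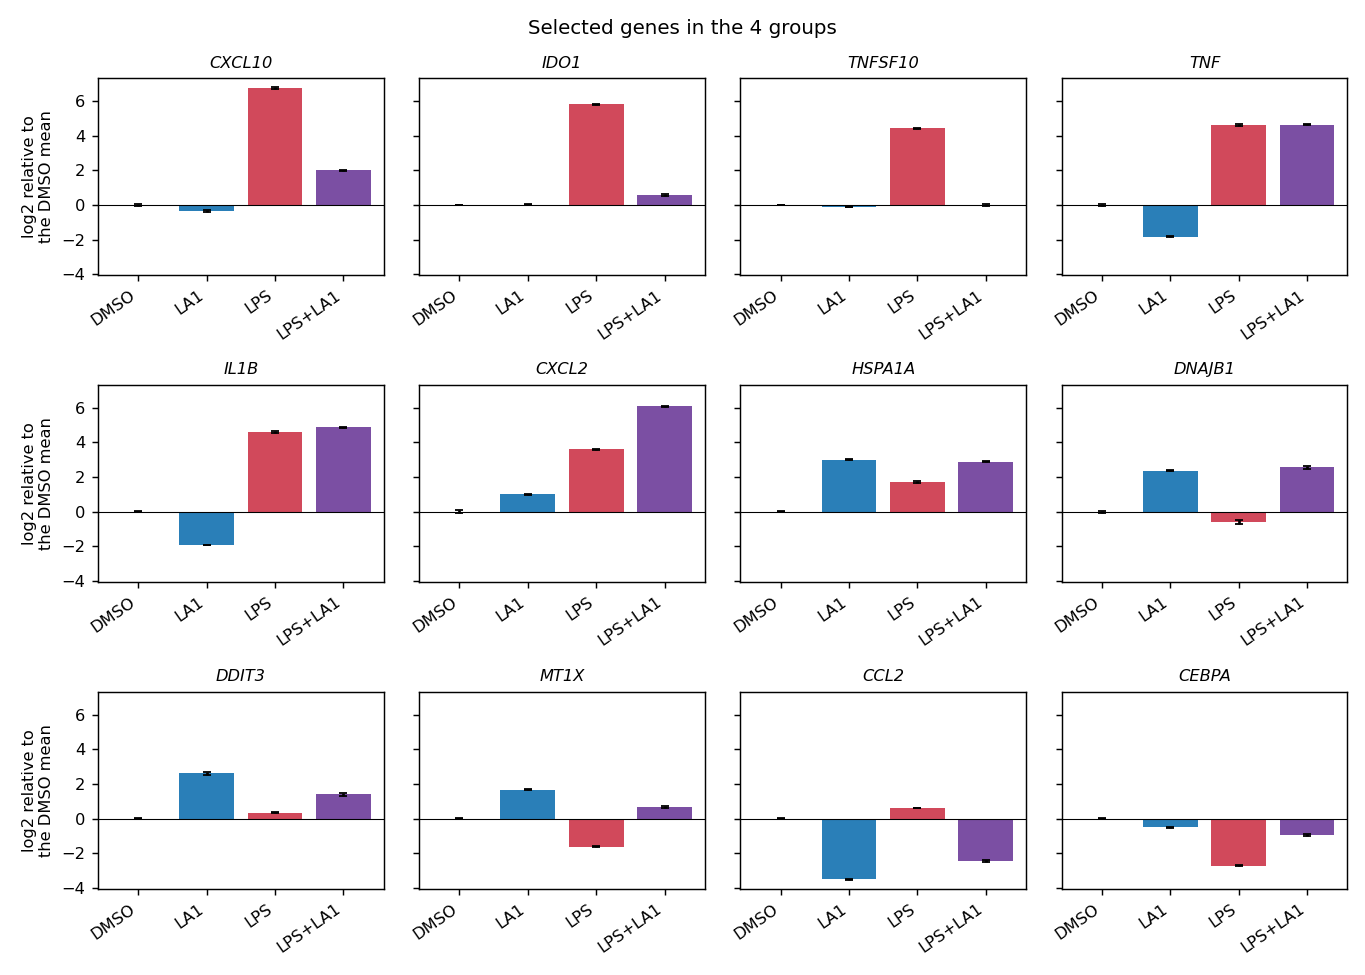
Group means of 12 genes picked after their values were seen, on the y axis as the log2 difference from the DMSO mean, with bars for DMSO, LA1, LPS and LPS+LA1 and error bars for the SD of 3 arrays. CXCL10, IDO1 and TNFSF10 were lower with LPS+LA1 than with LPS, by 4.75, 5.21 and 4.41, TNF differed by 0.05, and CXCL2 was higher by 2.49.

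LA1 against DMSO gives the effect of the compound on macrophages without LPS. HSPA1A, which encodes an inducible Hsp70 chaperone, was 8.06-fold higher (log2 change 3.01 ± 0.0415, SE, n = 3 per group, adjusted p = 1.30e-28), and its near-identical copy HSPA1B 7.82-fold (2.97), so the signal of these copies may be shared. DDIT3, the transcription factor CHOP of the integrated stress response, rose by 2.61, the co-chaperone gene DNAJB1 by 2.38, and DDIT4 and TRIB3 by 2.29 and 2.22. DUSP1, a phosphatase of MAP kinases (1.96), the metallothionein genes MT1X (1.67) and MT1E (1.62), ERRFI1 (1.51), CXCL8 (1.47) and GDF15 (1.31) were also higher, and 1 of the 2 MT1E probes passed. The largest decrease was that of CCL2, a chemokine that draws monocytes, which was 11.4-fold lower (−3.51 ± 0.0391, adjusted p = 8.08e-31). The cytokine genes IL1B (−1.92) and TNF (−1.83), PDK4 (−1.46), CCL8 (−1.44), the potassium channel gene KCNJ2 (−1.41), ZNF366 (−1.40), LPAR6 (−1.37), the cholesterol exporter ABCA1 (−1.36), MYC (−1.27), SLA (−1.24) and FOS (−1.22) followed. The SE of the 24 changes ran from 0.0385 to 0.0515. The 2 groups did not overlap for 30.2% of all genes, against 10% by chance.

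Of 17 heat shock and proteotoxic stress genes 13 were higher and 0 lower with LA1 (median 0.52, adjusted p = 2.99e-26), including BAG3 (1.27), while HSPE1 had a change of 0.16. Of 20 genes of the ATF4 amino acid response 15 were higher and 2 lower (median 0.35, adjusted p = 9.08e-19), with asparagine synthetase, ASNS, at 1.07. Of 12 metallothionein and metal transport genes 8 were higher and 0 lower (median 0.70, adjusted p = 2.02e-14), with MT1M at 1.22 and MT1G at 1.02, though cross-hybridisation between these similar genes cannot be excluded. Of 17 NRF2 antioxidant targets 8 were higher and 0 lower (median 0.09, adjusted p = 3.75e-06), with the heme oxygenase gene HMOX1 at 0.99, SRXN1 at 0.84 and GCLM at 0.71. In these 4 lists 14, 15, 8 and 8 were higher adjusted over the list alone.

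Of 32 interferon genes 21 were lower and 2 higher with LA1 alone (median −0.18, adjusted p = 1.78e-11), with MX1 at −0.96 and IFIT1 at −0.73. Of 13 LXR targets, genes of cholesterol export, 8 were lower and 0 higher (median −0.20, adjusted p = 7.43e-06), with ABCG1 at −0.39. Of 16 integrins and adhesion genes 8 were lower and 1 higher (adjusted p = 1.68e-05), led by ITGA5 (−0.65). The lower genes numbered 22, 8 and 8 adjusted over the list alone. Of 19 pro-inflammatory cytokines 3 were lower, IL1B, TNF and OSM (−0.31), and 16 did not pass (adjusted p = 0.00958; 3 lower adjusted over the list alone). Among genes with a range of at least 0.5 the cytokine list did not pass (adjusted p = 0.205, 0.00384 to 0.205 over its 7 camera alternatives). Of 20 antigen presentation and costimulation genes 11 were lower and 0 higher (adjusted p = 1.96e-06; 11 lower adjusted over the list alone). Of 19 NF-kB feedback and subunit genes 10 were lower and 4 higher (adjusted p = 0.00637; 10 lower adjusted over the list alone). These 2 lists kept their counts with housekeeping scaling but did not pass among genes with that range (camera, adjusted p = 0.117 and 0.342). Markers of T cells (adjusted p = 0.885), NK cells (0.885), B cells (0.137), neutrophils (0.845), dendritic cells (0.580) and platelets or erythroid cells (0.700) did not pass as lists. For T and NK cells the median was negative and the test positive. With housekeeping scaling 19 interferon and 7 LXR genes were lower, and the heat shock, ATF4, metallothionein, NRF2, integrin, cytokine and macrophage counts were the same. Of 18 macrophage and monocyte markers 7 were lower and 1 higher (adjusted p = 6.47e-05; 8 lower adjusted over the list alone), with CSF1R at −0.57, and that list did not pass among genes with a range of at least 0.5 (adjusted p = 0.137, 2.24e-05 to 0.137 over its 7 camera alternatives). At least 2-fold changes were seen for 55 genes, 29 higher and 26 lower, among 3878 that passed, 1819 higher and 2059 lower (53.1% lower, and 56.1% with housekeeping scaling).

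LPS+LA1 against LPS gives the effect of LA1 on LPS-treated macrophages. IDO1 was 37.1-fold lower with LA1 (−5.21 ± 0.0395, SE, n = 3 per group, adjusted p = 2.37e-35), and the chemokines CXCL9 and CXCL10 were 27.8-fold and 26.8-fold lower (−4.80 and −4.75). TNFSF10, the death ligand TRAIL, fell by 4.41, and CCL8 (−4.14), the guanylate-binding protein genes GBP4 (−3.95) and GBP5 (−3.50), and CCL1 (−3.93) were lower. The antiviral gene RSAD2 (−3.75), the cytokine gene IL27 (−3.56), the B cell survival factor TNFSF13B (−3.46) and CFB (−3.36) followed. The largest increases were those of MMP10, a secreted protease, which was 10.7-fold higher (3.42 ± 0.0409, adjusted p = 5.75e-31), DNAJB1 (3.18) and the neutrophil chemokine CXCL2 (2.49). DHDH (2.46), MT1X (2.29), PSMD5, which takes part in proteasome assembly (2.26), MYBPH (2.10), HSPA1B (2.07), the co-chaperone BAG3 (1.96), GEM (1.86), RGS2 (1.85) and BAMBI (1.83) followed. The SE of the 24 changes ran from 0.0386 to 0.0515. The 2 groups did not overlap for 38.8% of all genes, against 10% by chance.

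All 32 interferon genes were lower with LPS+LA1 than with LPS (median −1.95, adjusted p = 1.45e-59), from RSAD2 at −3.75 to IFIT2 at −0.75. Of 20 antigen presentation genes 15 were lower and 1 higher (adjusted p = 9.78e-11), with CD80 at −2.30, CD40 at −2.05 and HLA-B at −0.03. Of 22 antimicrobial effectors 14 were lower and 3 higher (adjusted p = 7.50e-08), including GCH1 (−2.42), ACOD1 (−2.29) and NCF1 (−2.06). Of 19 NF-kB feedback and subunit genes 15 were lower and 3 higher (median −0.43, adjusted p = 9.59e-09), with TRAF1 at −2.38, TNIP3 at −2.11 and TNFAIP3 at 0.09. In these 4 lists 32, 15, 14 and 15 were lower adjusted over the list alone, and 32, 18, 18 and 15 with housekeeping scaling. Averaged over each list on each array, the interferon list fell by 2.00 (95% interval −2.04 to −1.97) and the NF-kB list by 0.56 (−0.58 to −0.54). The exact permutation p of each, two-sided with n = 3 per group, was 0.1, the smallest that this number of arrays allows.

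Cytokine and chemokine genes went both ways. Of 19 pro-inflammatory cytokines 13 were lower and 4 higher (adjusted p = 5.73e-07), with EBI3 at −2.97, IL6 at −1.99 and IL23A at −1.59. TNF and IL1B, which LPS raised by 4.59 and 4.61, had changes of 0.05 (adjusted p = 0.443) and 0.26 (adjusted p = 3.58e-06) when LA1 was added. Of 24 chemokines 12 were lower and 5 higher (adjusted p = 9.29e-07), with CCL2 at −3.06 and CCL3 at −0.01. The lower genes were 13 cytokines and 12 chemokines adjusted over the list alone, and 14 and 18 with housekeeping scaling. TNF and IL1B were singled out after their values were seen.

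**Figure D2:**
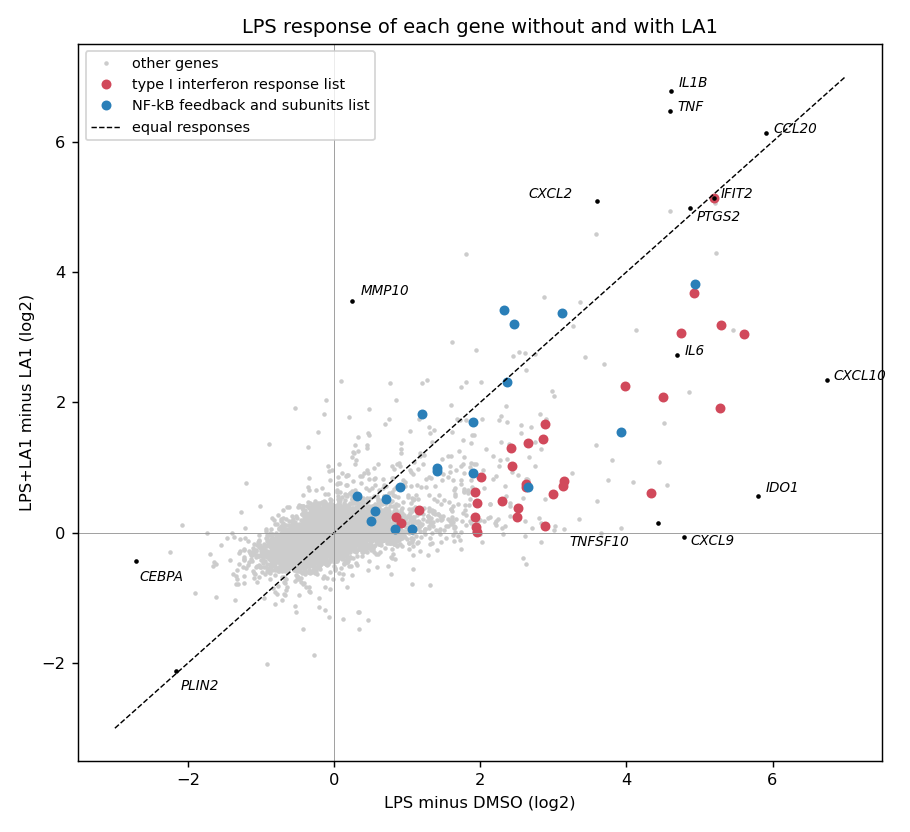
Log2 change of each of 19951 genes with LPS in the absence of LA1 (x axis, LPS minus DMSO) and in its presence (y axis, LPS+LA1 minus LA1); the dashed line marks equal responses, red points the 32 interferon genes and blue points the 19 NF-kB genes, and labelled genes were picked after their values were seen. CXCL10 moved from 6.74 to 2.34 and IDO1 from 5.80 to 0.57, while IL1B moved from 4.61 to 6.78.

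Of 17 heat shock genes 14 were higher and 2 lower with LPS+LA1 than with LPS (median 0.55, adjusted p = 9.13e-11), with HSPH1 at 1.68, and with housekeeping scaling 12 were higher and 2 lower (median 0.40). Of 20 oxidative phosphorylation genes 17 were higher and 0 lower (median 0.20, adjusted p = 0.000203), and with that scaling 6 were higher and 2 lower (median 0.06). Of 22 lysosome and autophagy genes 14 were higher and 1 lower (median 0.15, adjusted p = 0.000595), with WIPI1 at 0.62 and MAP1LC3B at 0.53, and with that scaling 9 were higher and 6 lower (median 0.005). Adjusted over the list alone, 14, 17 and 14 were higher. Of 20 ATF4 response genes 12 were higher and 3 lower (adjusted p = 0.0370; 12 higher adjusted over the list alone), with DDIT3 at 1.05 and NUPR1 at −2.60, and with housekeeping scaling 11 were higher and 7 lower. The ATF4 list did not pass with an estimated correlation (adjusted p = 0.0682) or among genes with a range of at least 0.5 (adjusted p = 0.359), 0.00197 to 0.359 over its 7 camera alternatives. Of 12 metallothionein and metal transport genes 6 were higher and 3 lower, and with housekeeping scaling 5 higher and 6 lower (adjusted p = 0.274; 6 higher and 4 lower adjusted over the list alone).

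Some markers of other cell types moved with the same arrays. Of 15 T cell markers 6 were lower and 1 higher (adjusted p = 0.000339), with IL7R at −1.85 and CD8A at −0.82. Of 13 NK cell markers 7 were lower and 1 higher (adjusted p = 0.000595), with GZMB at −0.74. Of 14 dendritic cell markers 4 were lower and 2 higher (adjusted p = 0.0133), with LAMP3 at −3.16. Adjusted over the list alone, 6, 8 and 4 were lower. Markers of B cells (adjusted p = 0.449), neutrophils (0.976) and platelets or erythroid cells (0.855, with a positive median and a negative mean and test) did not pass as lists. With housekeeping scaling 14 T cell, 12 NK cell and 11 dendritic cell markers were lower and 0 higher. That scaling turned B cell markers from 3 higher and 0 lower to 2 higher and 8 lower, neutrophil markers from 3 higher and 1 lower to 1 higher and 11 lower, and platelet and erythroid markers from 3 higher and 2 lower to 0 higher and 10 lower. Of 18 macrophage and monocyte markers 9 were lower and 4 higher (adjusted p = 0.0108; 10 lower adjusted over the list alone), with C1QC at −1.05 but CEBPA at 1.76 and MERTK at 1.32, and with that scaling 13 were lower and 3 higher. The macrophage list did not pass after housekeeping scaling (adjusted p = 0.116) or among genes with a range of at least 0.5 (adjusted p = 0.217), 0.0112 to 0.217 over its 7 camera alternatives.

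At least 2-fold changes were seen for 337 genes, 69 higher and 268 lower. Without that limit 6886 genes passed, 4273 higher and 2613 lower (37.9% lower), and with housekeeping scaling 14328 passed, 1947 higher and 12381 lower (86.4% lower). That scaling moved the median change of all genes to −0.13 and gave 47 genes at least 2-fold higher and 367 lower.

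**Figure D3:**
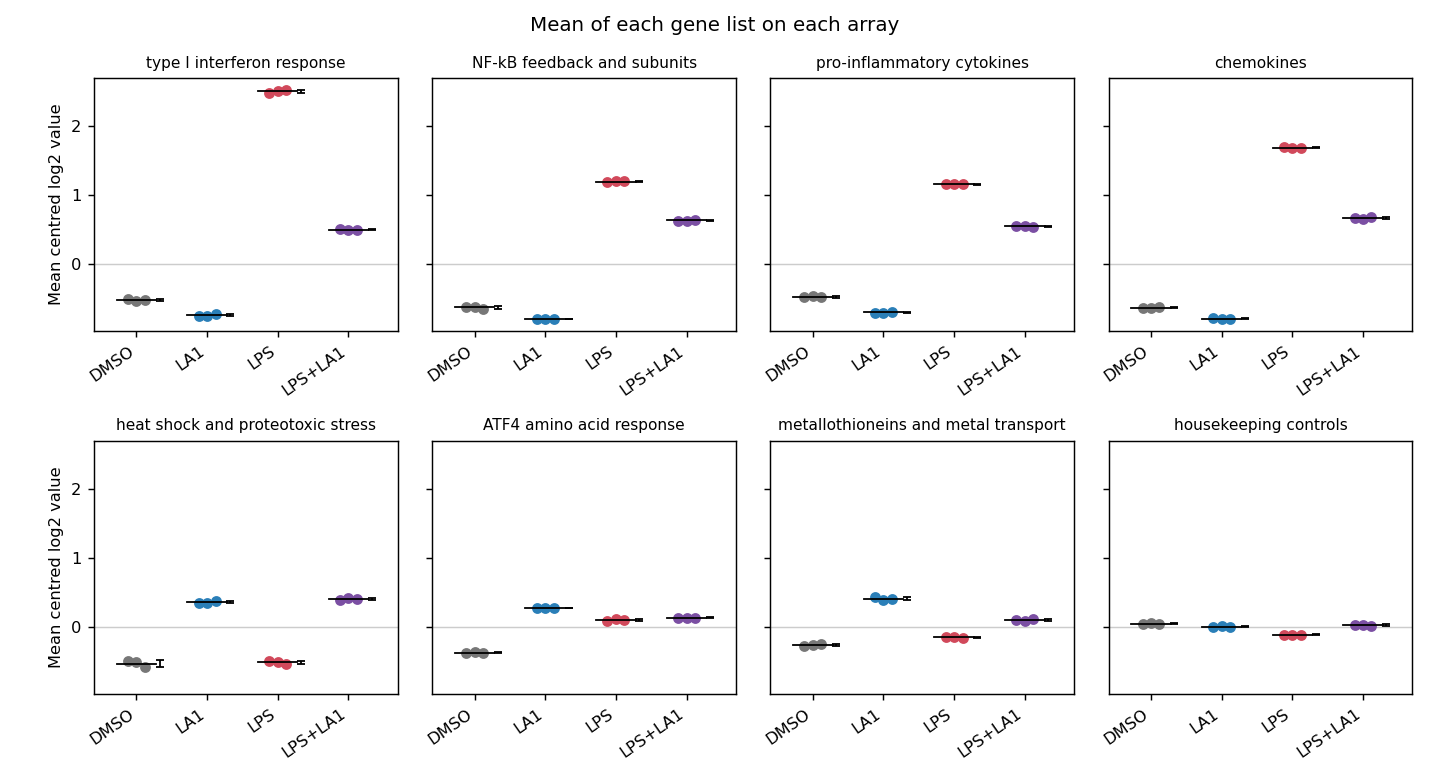
Mean centred log2 value of 8 gene lists on each array (y axis) in the 4 groups (x axis); points are arrays, lines group means and error bars the SD of 3 arrays. The interferon list averaged 2.50 with LPS and 0.50 with LPS+LA1 and the heat shock list −0.51 and 0.41.

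Genes raised by LPS were compared with those changed when LA1 was added. Of the 393 genes at least 2-fold higher with LPS, 344 were lower with LPS+LA1 than with LPS, 221 of them at least 2-fold, 35 were higher and 14 did not pass. These 2 comparisons share the LPS arrays. Independent lists would share 51.5. Simulated arrays with no LA1 effect gave 0 such genes, but adjusted p-values leave few calls in such arrays whether or not arrays are shared. At the unadjusted p that the passing genes reached, 20 simulations gave a mean of 2.70 and at most 12. They leave out the real effects, and part of the excess among smaller changes may come from the shared arrays. Of at least 2-fold falls they gave 0 at that p, against the 221 seen, which argues against shared arrays as the source of those 221. When genes were chosen on the arrays of 2 replicate numbers and measured on the third, the chosen genes had a median change with LPS+LA1 of −1.11, −1.13 and −1.16 against LPS (mean −1.14 ± 0.0278, SD, n = 3). In the same arrays their median change was 1.68 ± 0.0208 for LPS against DMSO, 0.46 ± 0.0150 for LPS+LA1 against LA1 and −0.02 for LA1 against DMSO. An exact sign-flip test of 3 values cannot give a p below 0.25. Of the 85 genes at least 2-fold lower with LPS, 71 were higher with LPS+LA1 than with LPS, where independent lists would share 18.2 and the simulations gave at most 3 at the unadjusted p. Of the rest 4 were lower and 10 did not pass. The held-out median of such genes was 0.52 ± 0.0180 (SD, n = 3) for LPS+LA1 against LPS, −1.17 ± 0.0306 for LPS against DMSO, −0.37 ± 0.0104 for LPS+LA1 against LA1 and −0.37 ± 0.0150 for LA1 against DMSO.

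LPS+LA1 against LA1 gives the LPS response in the presence of the compound. IL1B was 110.2-fold higher (log2 change 6.78 ± 0.0394, SE, n = 3 per group, adjusted p = 1.84e-38), TNF was 88.6-fold higher (6.47), and CCL20 (6.14), IFIT2 (5.13) and CXCL2 (5.09) followed. The largest decreases were those of PLIN2 (−2.12), TMEM119 (−2.01), the selenium carrier SELENOP (−1.88), S100A8 (−1.48) and the complement gene C1QC (−1.47), and 1 of the 2 SELENOP probes passed. At least 2-fold changes were seen for 168 genes, 150 higher and 18 lower, among 5179 that passed, 2041 higher and 3138 lower (60.6% lower, and 63.0% with housekeeping scaling). The 2 groups did not overlap for 33.7% of all genes, against 10% by chance.

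The interaction tests whether the LA1 effect differed with and without LPS. The LA1 effect was more negative with LPS for IDO1 (−5.23 ± 0.0558, SE, n = 3 per group, adjusted p = 2.54e-31), CXCL9 (−4.85), CXCL10 (−4.40), TNFSF10 (−4.28) and CCL1 (−3.85). It was more positive for MMP10 (3.31 ± 0.0579, adjusted p = 1.78e-26), MYBPH (2.46), CEBPA (2.27), MYC (2.25) and PSMD5 (2.24). Of 32 interferon genes 31 had a more negative LA1 effect with LPS (median −1.77, adjusted p = 3.98e-63), and IFIT2 had a value of −0.06. Of 20 ATF4 genes 12 had a more negative LA1 effect with LPS and 0 a more positive one (median −0.30, adjusted p = 1.85e-09), with NUPR1 at −2.98 and DDIT3 at −1.55. Adjusted over the list alone, 31 and 13 were more negative, and with housekeeping scaling 32 and 14. With LPS against DMSO 14 of the 20 ATF4 genes were higher and 2 lower (camera, adjusted p = 1.01e-06), and with housekeeping scaling 17 and 2. The ATF4 list averaged −0.37 with DMSO, 0.28 with LA1, 0.10 with LPS and 0.13 with LPS+LA1. Its LA1 effect with LPS is thus measured from a higher value. The same holds for the interferon list, which averaged −0.51 with DMSO, −0.74 with LA1, 2.50 with LPS and 0.50 with LPS+LA1. It also holds for IDO1, CXCL9, CXCL10, TNFSF10 and CCL1, which LPS raised by 3.93 to 6.74. How far such genes could fall without LPS cannot be told from centred values. The heat shock list did not pass (8 more positive, 5 more negative, adjusted p = 0.506), with HSPA1A at −1.83 and HSPH1 at 0.71, and with that scaling 6 were more positive and 5 more negative. At least 2-fold differences were seen for 318 genes, 56 positive and 262 negative, among 5437 that passed, 3315 positive and 2122 negative (39.0% negative). With housekeeping scaling 9122 passed, 1530 positive and 7592 negative (83.2% negative), and 34 positive and 348 negative differences were at least 2-fold.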

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

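The tests of shared LPS arrays, of a uniform loss of transcripts and of near-identical copies, and the limit of 0.5 on the log2 scale for opposite effects, were chosen after the results were seen, as was the scaling on housekeeping genes.

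Among the genes named above, 7 had LA1 effects in opposite directions without and with LPS, both of at least 0.5, with the difference tested as the interaction. CEBPA had a log2 change with LA1 of −0.51 without LPS and 1.76 with it, a difference of 2.27 ± 0.0566 (SE, limma, adjusted p = 5.61e-23). MYC went from −1.27 to 0.98 (difference 2.25) and FOS from −1.22 to 0.98 (2.20). MERTK went from −0.64 to 1.32 (1.96) and RASL11B from −0.93 to 0.81 (1.74). PRAG1 went from −0.66 to 0.70 (1.36) and CHD9 from −0.60 to 0.59 (1.19). Except for MYC, these genes were among the 12 largest decreases with LPS, and MYC was also lower with LPS (−0.89). The LA1 effect with LPS of all 7 is thus measured from a lower value.

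The 17108 probes that the annotation table did not list were outside the comparisons of genes. At least 2-fold changes were seen for 56 of them with LPS, 13 with LA1 and 35 with LPS+LA1 against LPS.

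The fall of LPS-induced genes when LA1 was added was weighed against 3 technical explanations. A fall created by choosing and measuring genes on the same LPS arrays is argued against by the held-out median of −1.14, where other arrays were used for the choice. After scaling on housekeeping genes the held-out median was −1.15. The housekeeping median differed by only 0.15 between LPS+LA1 and LPS. That scaling could therefore not have removed the fall, and it does not decide on a scaling error. A loss of all induced transcripts alike is argued against as the whole cause by 28 of the 393 induced genes (7.12%). These were higher as deposited and with housekeeping scaling, among them CXCL2, NFKBIZ and IL1B. As deposited, 6 of the 393 were at least 2-fold higher. A rise with LA1 alone, seen for CXCL2 (1.00) but not for IL1B (−1.92), could outweigh such a loss, so the count does not exclude it as a part. Cell death and RNA quality are not judged by these genes, since neither need lower all transcripts alike. An error that differs with signal strength, which centred values cannot show, and a slide or day, which is not given, stay open, and quantitative PCR of CXCL10, IDO1, CXCL2 and IL1B in separate cultures would test them.

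More genes passed as lower than as higher with LPS, and the direction of this excess depended on the scaling. After scaling on housekeeping genes 20.0% of the passing genes were lower, against 65.7% as deposited. The median of the housekeeping genes fell by 0.14 on the log2 scale, with GAPDH at −0.34, and that shift alone turns many small changes, so it does not tell a scaling error from a response of those genes to LPS. No biological reading of the excess is offered.

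The rise of heat shock genes with LA1 was weighed against shared signal, and was also read after housekeeping scaling. Signal shared between the HSPA1 and HSPA6 copies is argued against as the whole cause by 10 of the 13 other members that rose, 2 of them at least 2-fold. Most of that count follows from the 13 of 17 members already found higher, so it is no separate test. With housekeeping scaling 13 list genes stayed higher and 0 lower (median 0.51), but that scaling moved the median change of all genes only to −0.003. It therefore does not decide on a scaling error, and an error that differs with signal strength was not tested. No biological reading of the rise is offered, and HSPA1A and BAG3 protein in separate cultures would test whether it is real.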

How the results depend on the processing

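Of the alternatives below, the housekeeping scaling and the filter on genes that vary little were added after the data were seen. With the 2-fold limit, 478 genes passed for LPS against DMSO, 55 for LA1 against DMSO, 337 for LPS+LA1 against LPS, 168 for LPS+LA1 against LA1 and 318 for the interaction, fewer by construction. Housekeeping scaling gave 14188 genes for LPS against DMSO, 14328 for LPS+LA1 against LPS and 9122 for the interaction, from a shift of all genes. The filter on a range of at least 0.5 kept 3611 genes and gave 3428, 2349, 3323, 2807 and 3042 calls in the order above, from fewer genes tested, and 7 lists for LA1 against DMSO in place of 13. Since 3428 of the 3611 passed for LPS against DMSO, lists were there compared mostly with genes that the treatments changed. The test fry, which asks only whether a list's genes move one way, gave 38 lists for LPS against DMSO, 36 for LA1 against DMSO and 37 for the interaction. The held-out median was −1.84 for genes chosen at a log2 change of at least 2 and −0.26 for genes chosen by adjusted p alone, from stronger and weaker induction by construction.

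Each count stayed within 1.5 times its reported value when arrays were left out. The ranges were 6737 to 7636 genes for LPS against DMSO, 2858 to 3939 for LA1 against DMSO, 6043 to 6881 for LPS+LA1 against LPS, 4213 to 5235 for LPS+LA1 against LA1 and 4387 to 5266 for the interaction, and for lists 22 to 23, 13 to 14, 22 to 25 and 21 to 24, LPS+LA1 against LA1 having no list test. Dropping 1 array leaves a group of 2, whose spread is pooled with the other groups. Genes chosen by size of change lost no call and changed no direction under the alternatives that give 1 value per gene, but with each probe tested by itself 1 probe each of DYRK2 with LPS, MT1E with LA1 and SELENOP with LPS+LA1 against LA1 did not pass. With an estimated correlation 21 of 22, 13 of 13, 20 of 24 and 19 of 22 lists held in those 4 comparisons. Lost were cholesterol biosynthesis with LPS, NRF2, ATF4, fatty acid synthesis and p53 targets with LPS+LA1 against LPS, and alternative activation, p53 targets and dendritic cell markers in the interaction.

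Samples with the same replicate number share only a number. Correlations of their deviations ran from −0.0416 to 0.0222, and 2 of 12 arrays correlated best with their own number. With the replicate number as a block 7588, 3847, 6862, 5131 and 5380 genes passed. Background correction, normalization, detection filters and a slide block were not run, since no signals or slides could be tied to samples. How far signal stood over background is unknown, which limits what can be said of weakly expressed genes.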

Other observations

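The housekeeping scaling and the filter on range were chosen after the results were seen, and the splits of the arrays were planned before.

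Canonical histone genes, not described above, were higher when LA1 was added. With LPS+LA1 against LPS 12 of 16 were higher and 0 lower (median 0.24, camera, adjusted p = 3.37e-05), with H2AC6 at 0.91 and H2BC5 at 0.87, and with housekeeping scaling 8 were higher and 2 lower (median 0.10). With LA1 alone 8 of 16 were higher and 0 lower (adjusted p = 0.00168), led by H4C3 (0.56), though that list did not pass among genes with a range of at least 0.5 (adjusted p = 0.137, 0.000709 to 0.137 over its 7 camera alternatives) and with housekeeping scaling 7 were higher. The higher genes numbered 12 and 9 adjusted over the list alone. Apoptosis regulators split: with LPS+LA1 against LPS 9 of 15 were lower and 2 higher (adjusted p = 3.72e-05; 9 lower adjusted over the list alone, 12 with housekeeping scaling), with BCL2L1 at −0.91 and BID at −0.75 but PMAIP1 at 0.96.

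The LA1 effects without and with LPS share no arrays. Across genes, which are not independent replicates, their log2 changes had a Pearson r of 0.294. Of 2798 genes past the threshold in both, 1879 moved in the same direction and 919 in opposite directions, and both exceeded what independent lists would share. Higher in both were 1126 (389.6 if independent) and lower in both 753 (269.7), while 256 were higher without and lower with LPS (238.2) and 663 lower without and higher with LPS (441). At least 2-fold changes in both were seen in the same direction for 20 genes and in opposite directions for 0. These counts are from the values as deposited and were not repeated with housekeeping scaling. That scaling moved the share of lower genes among those passing for LPS+LA1 against LPS from 37.9% to 86.4%. The counts by direction therefore depend on the scaling.

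Other splits of the arrays were also counted, but they do not stand for arrays without a treatment effect. For LPS against DMSO 1 of the 10 splits of the 6 arrays, the real one, gave as many as 7607 genes, and the highest other gave 0. The same was seen for LA1 against DMSO (3878 genes, highest other 0), LPS+LA1 against LPS (6886, highest other 0) and LPS+LA1 against LA1 (5179, highest other 0). For lists, 22, 13 and 24 passed in the first 3 comparisons, and the highest other splits gave 17, 6 and 12. Each of these other splits mixes arrays of both groups, so a treatment effect enters their spread and leaves few genes to pass. Lists that passed in them may carry part of that effect. Too few splits also exist for a share under 0.05. For the interaction, 1 of 100 splits of the 12 arrays, the real one, gave as many as 5437 genes and 22 lists, against 3148 and 20 at most in the others. Those splits mix arrays with and without LPS, so the LPS effect enters their spread and they do not stand for arrays without an interaction. Chance was not judged from any of these splits.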
